A study of Mus musculus with 12 samples.

How the data were processed

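RNA was measured in whole blood of CB17-SCID mice carrying xenografts of HT1376, a human bladder cancer cell line. The mice had received vehicle or 35 mpk (mg per kg) of CPI-0209 by mouth once daily for 11 days. There were 12 libraries in 4 groups of 3: vehicle, and CPI-0209 with blood taken 1, 6 or 24 h after the last dose. The labels do not say when the vehicle mice were bled, nor whether replicate numbers mark a shared cage or day.

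Per the labels, RNA was extracted with a PAXgene blood kit, libraries were made after ribosomal RNA depletion, and reads were paired-end on an Illumina HiSeq. The authors supplied counts per gene as whole numbers for 55367 mouse Ensembl genes, not scaled to library size. Their notes name RSEM without a version, so the counts may be rounded estimates, which the sources used here do not state. The notes list a human genome build although the gene identifiers are mouse, and the annotation release, aligner and strand are not given in the sources used here. Positions were taken from the GENCODE M21 annotation of GRCm38, which held 55111 of the identifiers. Library totals ran from 6496573 to 9978215 counts. Intervals on counts cover counting error only.

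Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Low counts were removed with filterByExpr by group, which left 13384 genes. Library sizes were scaled by TMM. A quasi-likelihood model with 4 group means was fitted to all 12 libraries, and 7 contrasts were tested: each time against vehicle, the mean of the 3 times against vehicle, and each pair of times. A further F test asked for any difference among the 3 times. P values were adjusted by Benjamini-Hochberg over the 13384 genes, with a threshold of 0.05, and every adjusted p for a gene is from this edgeR model unless another tool is named. An exact permutation test of 3 libraries against 3 cannot give a two-sided p under 0.1. Levels are library-scaled counts (CPM, as edgeR computes them on TMM-scaled sizes), as mean ± SD with n = 3. Log2 fold changes are followed by their standard error (SE), and list means are means of log2 CPM with a prior count of 2.

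The groups, comparisons, tests, gene lists, rule for named genes and alternatives, apart from those said to be chosen later, were fixed before the data were examined. In each comparison with vehicle, genes had to pass the threshold, have all treated CPM above or all below the vehicle CPM (10% of unchanged genes do so by chance with 3 against 3) and have a mean log2 CPM of at least 1. Of these the 12 with the largest rise and the 12 with the largest fall were named. Between times the 6 largest in each direction were named. Where none passed in a direction, the 3 with the smallest p were given as not passing. Predicted names were counted and not named. Ezh2, Ezh1, Eed and Suz12 were always given, and up to 4 members with the smallest p from each list described. Some results that these rules would name are not reported here.

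There were 43 lists for blood cell types, chromatin complexes and pathways, written from textbook knowledge. The 41 with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted within each contrast. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other tested genes, whereas fry asks whether the members move, on balance, in 1 direction.

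Alternatives were DESeq2 size factors, leaving out haemoglobin genes, no filter, a filter of 5 CPM in 3 libraries, DESeq2 without independent filtering, limma-voom, only the groups compared, the replicate number as a block, and each library left out in turn. A reticulocyte covariate (the mean log2 CPM of the reticulocyte list) and scaling by library totals alone were chosen after seeing the data. The 3 comparisons with vehicle share their controls, which cannot be split into groups of 2 or more. For this reason 50 simulations of unchanged groups were run. All 12 libraries, vehicle included, were drawn from the same mean and dispersion per gene, each gene independently. The wider spread at 24 h and any correlation between genes were not simulated. Tested on simulated data, the model recovered 32% of 1-unit and 87% of 2-unit log2 changes at 24 h against vehicle, with 6 false calls among 13113 genes, and none in an unchanged comparison. All 12 libraries were used.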

Results

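CPI-0209 (tulmimetostat) is an inhibitor of EZH2 and EZH1, the enzymes that methylate histone H3 at lysine 27 within Polycomb repressive complex 2 (PRC2). The series asked how it changed the transcripts of whole blood in tumour-bearing mice. Total counts were 7701833, 8530531 and 7653152 in the 3 vehicle libraries, 6739993, 8781149 and 8535356 at 1 h, 8753317, 9962024 and 9978215 at 6 h, and 6496573, 7653753 and 7487020 at 24 h. Adult globin transcripts took 0.109% to 0.455% of the counts. The mean log2 CPM of 35 reticulocyte genes was 7.58, 7.61 and 7.88 in vehicle, 8.15, 8.30 and 8.06 at 1 h, and 9.13, 9.01 and 8.99 at 6 h. The 24 h libraries lay far apart, at 7.01, 7.56 and 8.66. TMM factors were 0.77 to 0.81 at 6 h and 1.03 to 1.12 in vehicle.

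The first comparison asked which genes differed from vehicle at every collection time. There were 7 genes called higher at 1, 6 and 24 h: Runx1t1, Mapre3, Slc4a5, Rragd, Scd1, Car8 and Hsd3b6. Runx1t1, a transcriptional corepressor, rose from 8.12 ± 1.31 CPM in vehicle to 44.4 ± 4.84 at 1 h, 93.4 ± 12.4 at 6 h and 44.6 ± 14.3 at 24 h (SD, n = 3). Mapre3, which binds growing microtubule ends, rose from 3.09 ± 0.519 CPM to 29.0 ± 3.45, 52.5 ± 26.5 and 26.9 ± 7.21. Rragd, a Rag GTPase of amino acid signalling, rose from 4.11 ± 1.35 CPM to 26.2 ± 4.18, 40.7 ± 6.41 and 13.8 ± 4.02. Scd1, a fatty acid desaturase, rose from 7.35 ± 2.07 CPM to 26.7 ± 4.38, 50.5 ± 11.99 and 23.3 ± 1.62.

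The log2 fold change of Runx1t1 (ENSMUSG00000006586, GRCm38 chromosome 4, 13743436 to 13893649) was 2.45 (SE 0.25, adjusted p = 0.00056) at 1 h, 3.52 (SE 0.25, adjusted p = 1.4e-05) at 6 h and 2.45 (SE 0.25, adjusted p = 0.0011) at 24 h. That of Mapre3 (ENSMUSG00000029166, chromosome 5, 30814641 to 30866106) was 3.23 (SE 0.35, adjusted p = 0.00081), 4.08 (SE 0.35, adjusted p = 6.3e-05) and 3.12 (SE 0.35, adjusted p = 0.0019). With only the 2 groups compared, 1 gene in all was called at 24 h, so at least 1 of these 2 genes lost its call there. In every fit that left out 1 library, both genes passed at each time. Calls of the others were less firm: at 24 h Hsd3b6 lost its call in 10 of these 12 fits, Rragd in 9, and Slc4a5, Car8 and Scd1 in 3 each, and at 1 h Hsd3b6 lost it in 6 and Car8 in 2. Slc4a5, a bicarbonate cotransporter (chromosome 6, 83219828 to 83304945), had 5 counts over the vehicle libraries and 137, 430 and 102 at 1, 6 and 24 h. The ratios were 27.8 (95% exact binomial interval 11.6 to 87.0), 98.2 (41.8 to 304.1) and 21.7 (9.002 to 68.3). These intervals leave out the choice of fit. Over the alternatives tried for named genes its log2 fold change ran from 4.17 to 8.46 at 1 h. At 6 h it ran from 5.94 to 10.2, and at 24 h from 3.81 to 8.10. Car8, related to carbonic anhydrases, went from 0.765 ± 0.550 CPM to 6.20 ± 0.238, 7.98 ± 3.14 and 7.24 ± 1.57. Hsd3b6, a steroid dehydrogenase, went from 0.824 ± 0.535 CPM to 11.1 ± 1.34, 18.9 ± 3.93 and 11.1 ± 9.76.

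**Figure D1:**
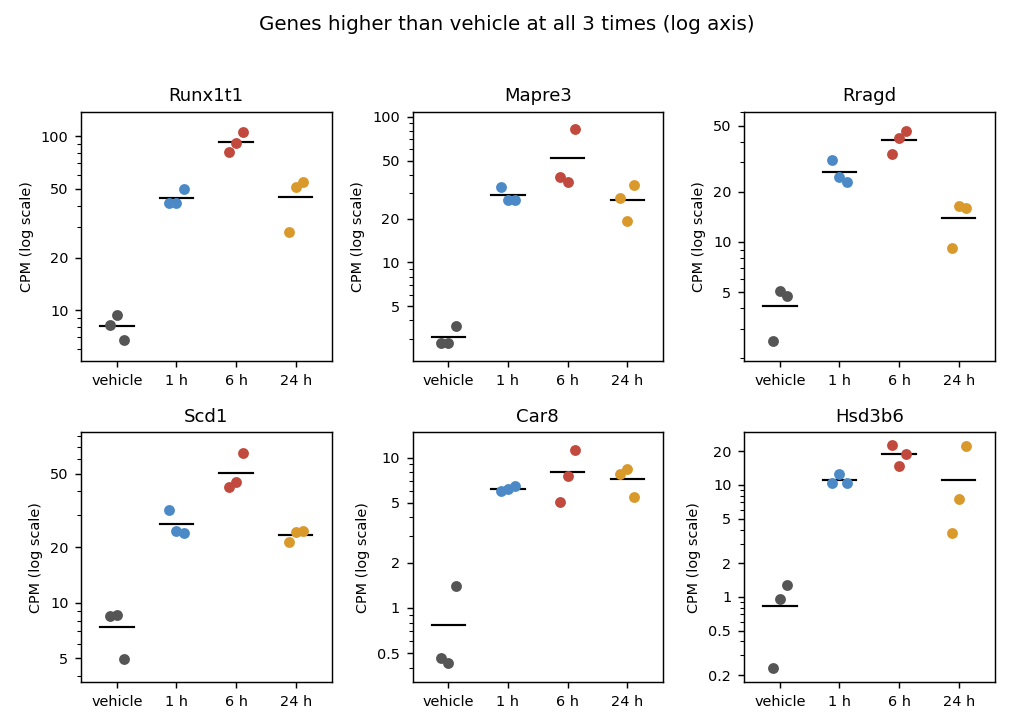
CPM on a log scale for Runx1t1, Mapre3, Rragd, Scd1, Car8 and Hsd3b6 in vehicle and 1, 6 and 24 h after the last dose of CPI-0209. Points are libraries (n = 3 per group) and lines are group means, with every treated point above the vehicle points of its gene.

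Calls at different times were shared more often than the product of the list sizes gives, which does not allow for the shared vehicle libraries. Genes called higher at both 1 and 6 h numbered 17 (0.974 expected), at 1 and 24 h 7 (0.0251 expected), and at 6 and 24 h 13 (0.568 expected). Simulated libraries with no changed gene gave means of 0, 0.02 and 0 shared calls. With no gene changed, few calls can arise at any time. These means therefore do not measure what the shared controls add among called genes. Across all 13384 genes, which are not independent replicates, fold changes correlated at r = 0.47 for 1 and 6 h, 0.56 for 1 and 24 h and 0.47 for 6 and 24 h. The simulated means from shared controls alone were 0.49, 0.50 and 0.49. Covariance exceeded the simulated mean by 0.0739, 0.0531 and 0.0839. The share of genes with the same sign was 60.3%, 69.2% and 59.0%, against simulated means of 66.5%, 66.6% and 66.6%, so it was lower than simulated in both pairs with 6 h. Of the 551 genes called higher at any time, 520 were called at 6 h alone, and of the 106 called lower, 104 were called at 6 h alone.

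The mean of the 3 times against vehicle gave 118 genes higher and 7 lower, including 3 with predicted names. The largest rises with 9 of 9 treated libraries above vehicle were in Slc4a5 (5.19, SE 0.60), Hsd3b6 (3.99), Rhbdf1 (3.86), Cystm1 (3.75), Mapre3 (3.48) and Car8 (3.22), followed by Gpd1 (2.95), Runx1t1 (2.80), Ccdc92b (2.59), Rragd (2.57), Pycr1 (2.51) and Pcx (2.49), all with adjusted p of 0.018 or lower. Gpd1, Pycr1 and Pcx are enzymes of glycerol phosphate, proline and pyruvate metabolism. Of the 7 genes that fell, the naming rule picked 4: Sart1 (-1.47, SE 0.32), a splicing factor, Atf3 (-0.94, SE 0.17), a stress-induced transcription factor, Epc1 (-0.76, SE 0.15), a subunit of a histone acetyltransferase complex, and the pseudogene Gad1-ps (-0.67, SE 0.14). Of the 12 fits that left out 1 library, Gad1-ps lost its call in 9, Sart1 in 8, Epc1 in 5, Atf3 in 3, Pycr1 in 2, and Hsd3b6, Rhbdf1, Cystm1 and Ccdc92b in 1 each.

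Of 35 reticulocyte genes, 7 rose in this mean, and 13 rose adjusted over the list alone. They included Gata1 (1.18) and Epb42 (2.16). The list's median was 0.61 (camera adjusted p = 5.1e-16, with adjusted p = 0.78 with an estimated correlation). Among the other lists called, Thbs1 (0.94) of 30 platelet genes and Blvrb (1.58) of 19 haem and iron genes passed, and Atf3 of 23 immediate early genes. Adjusted over the list alone, 3, 5 and 3 genes passed (adjusted p = 0.82, 0.82 and 0.81 with an estimated correlation). The remaining lists called were adult globins (0 of 4, with 1 adjusted over the list alone) and stem and progenitor markers (0 of 15, with 4), both toward higher, and classical monocyte markers (0 of 20, with 3), neutrophil secondary granule genes (0 of 19, with 0) and histone genes (0 of 36, with 0), all toward lower. Their adjusted p with an estimated correlation was 0.55, 0.55, 0.78, 0.82 and 0.82. Outside the lists called, Asns (1.57), Lat (0.78) and Hsp90ab1 (0.88) rose among stress response, T cell and heat shock genes. With library totals alone 10 reticulocyte, 2 haem and iron and 2 stress response genes were higher, 1 secondary granule gene was lower, and 0 T cell and 0 heat shock genes passed. The gene count was 14, 36 and 50 without vehicle replicate 2, 1 or 3. It was 80 and 71 without 1 h replicate 1 or 3, 78 without 6 h replicate 1, and 357 and 241 without 24 h replicate 1 or 3.

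At 1 h, 24 genes were higher than in vehicle and 2 were lower. Among genes that respond to glucocorticoids, Fkbp5, a cochaperone of the glucocorticoid receptor, rose from 24.4 ± 12.8 to 123 ± 7.16 CPM, and Klf9, a transcription factor, rose from 22.6 ± 3.35 to 56.5 ± 9.19 CPM (SD, n = 3). At 6 and 24 h Fkbp5 stood at 27.7 ± 9.20 and 32.4 ± 2.74 CPM. The other named rises were in Slc4a5 (4.70), Hsd3b6 (3.74), Rhbdf1 (3.497), Mapre3 (3.23), Car8 (3.03), Ptpn14 (2.71), Rragd (2.66), Gpd1 (2.63), Ccdc92b (2.59), Pcx (2.504), Runx1t1 (2.45) and Rundc3a (2.35). Epc1 (-1.02, SE 0.19) and Hrh2 (-0.98, SE 0.16), a histamine receptor, fell. Among the 12 fits that left out 1 library, Epc1 lost its call in 10, Rhbdf1 in 8, Rundc3a in 7, Hrh2 in 6, Ptpn14 and Gpd1 in 5, Ccdc92b in 4 and Pcx in 1. Epc1 also lost it with DESeq2 size factors, and Epc1 and Rhbdf1 with the replicate block. No gene was called lower in the fits without a vehicle or a 1 h library.

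Of 22 glucocorticoid-response genes, Fkbp5 (2.34, SE 0.32, adjusted p = 0.0065) and Klf9 (1.32, SE 0.19, adjusted p = 0.0066) passed over all genes. Adjusted over the list alone, 7 passed higher and 1 lower. Ddit4 (1.16, adjusted p = 0.086) and Per1 (2.19, adjusted p = 0.12) did not pass over all genes. The list's median was 0.51 (camera adjusted p = 4.5e-07, with adjusted p = 0.53 with an estimated correlation). Per1 was also the leading member of 15 core clock genes, of which 0 passed over all genes and 2 adjusted over the list alone (camera toward higher, adjusted p = 0.00047, and adjusted p = 0.53 with an estimated correlation). Fkbp5 lies on chromosome 17, 28399094 to 28517527, on the minus strand. The predicted genes Gm49838 (3.80) and Gm22146 (2.70) lie inside it, and were chosen for naming after their values were seen.

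**Figure D2:**
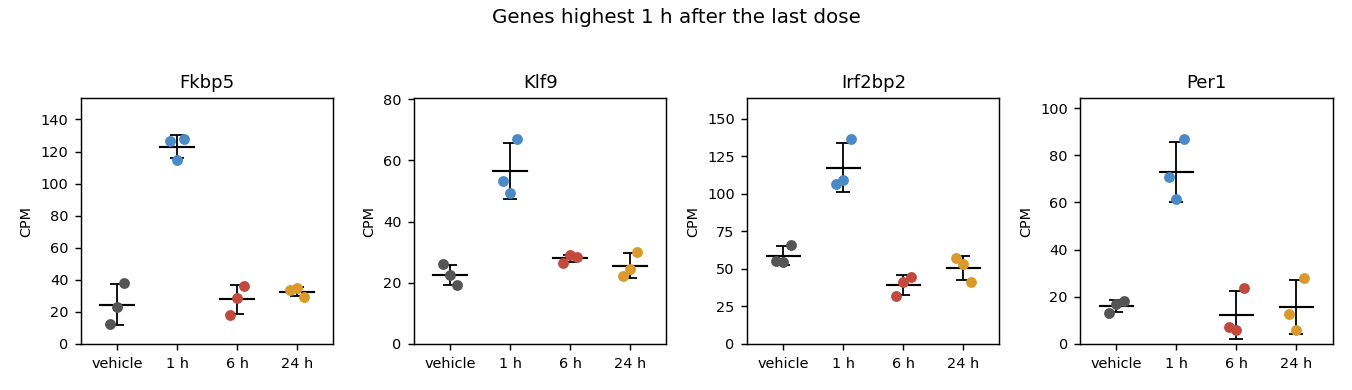
CPM of Fkbp5, Klf9, Irf2bp2 and Per1 by group, with points for libraries and bars for the mean ± SD (n = 3). The 1 h libraries of Fkbp5 average 123 CPM against 24.4 in vehicle, and the rise of Per1 did not pass the test.

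Of the 35 reticulocyte genes, 0 passed at 1 h over all genes and 11 were higher adjusted over the list alone, with a median of 0.36 (camera adjusted p = 8.7e-09, with adjusted p = 0.70 with an estimated correlation). Scaled by library totals alone, 8 of them passed higher. Epb42 had 1.98 (adjusted p = 0.056) and Trim58 1.33 (adjusted p = 0.086). Lists toward lower were 28 mature neutrophil genes (median -0.26, adjusted p = 0.74 with an estimated correlation), 19 secondary granule genes (-0.59, 0.57), 36 histone genes (-0.44, 0.70) and 77 ribosomal protein genes (-0.14, 0.82). None of their members passed over all genes in edgeR. Adjusted over the list alone, 1 neutrophil gene was higher and 3 lower, and 0 of the other lists passed. The neutrophil list lost its call and turned direction without vehicle replicate 3 (adjusted p = 0.60), and lost its call without 1 h replicate 1 (adjusted p = 0.074).

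The count of 26 genes at 1 h was 15 and 7 without vehicle replicate 1 or 2, and 14, 12 and 14 without 1 h replicate 1, 2 or 3. It was 127 and 165 without 24 h replicate 1 or 3, and DESeq2 called 152 genes where limma-voom called 17.

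At 6 h, 543 genes were higher than in vehicle and 105 were lower, including 50 with predicted names. Epb42, a membrane skeleton protein, rose from 125 ± 24.7 to 1112 ± 127 CPM. Slc4a1, the anion exchanger of red cells, rose from 1697 ± 294 to 7451 ± 372 CPM (SD, n = 3). Of the 35 reticulocyte genes, 17 rose over all genes and 26 adjusted over the list alone, with a median of 1.24. Gata1 (1.72, SE 0.20), Epb42 (3.15, SE 0.39), Ank1 (1.91) and Car2 (2.74) had the smallest p. Alas2, which starts haem synthesis, had 0.63 (adjusted p = 0.31) and did not pass. Camera gave an adjusted p of 2.7e-28, with adjusted p = 0.49 with an estimated correlation, and fry gave 0.057.

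**Figure D3:**
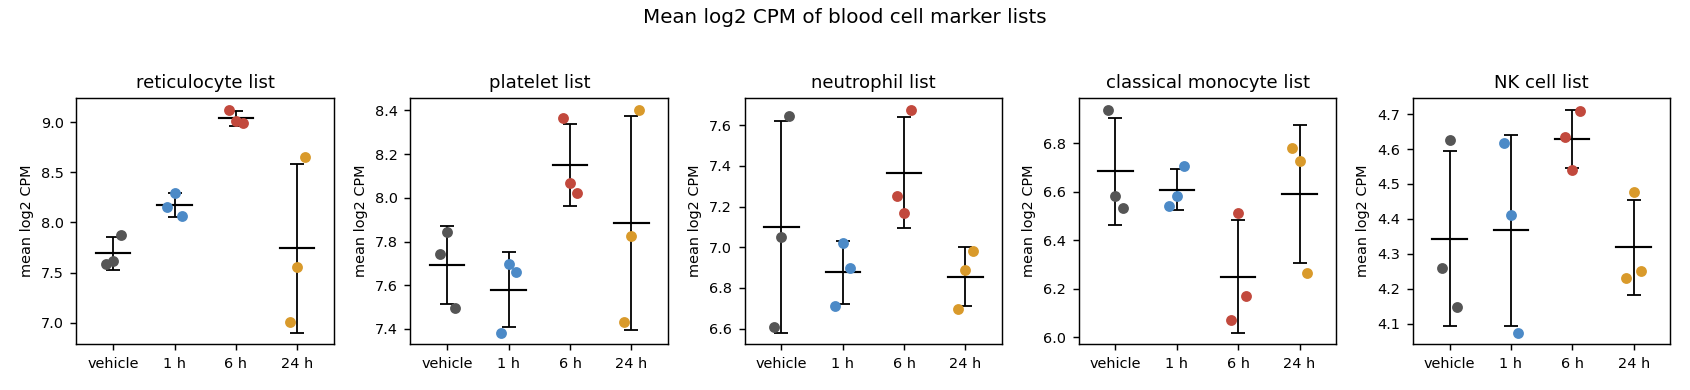
Mean log2 CPM of 5 marker lists for blood cells by group, with points for libraries and bars for the mean ± SD (n = 3). The reticulocyte list is 8.99 to 9.13 at 6 h against 7.58 to 7.88 in vehicle, and its 24 h libraries run from 7.01 to 8.66.

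Of 19 haem and iron genes 6 rose at 6 h, and 8 adjusted over the list alone, with Blvrb (2.46), Alad (1.57) and Nqo1 (2.28) among them and adjusted p = 0.49 with an estimated correlation. There were 6 higher and 3 lower with library totals alone. Of 4 adult globins, Hbb-bt (1.38) and Hbb-bs (1.52) rose, and all 4 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation, fry adjusted p = 0.013). The labels name only ribosomal RNA depletion, and whether globin RNA was removed as well is not given in the sources used here, so the cause of the globin values stays open. Of 30 platelet genes, Thbs1 (1.44) and Gfi1b (0.83) rose, and 2 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Of 15 stem and progenitor markers, Kit (1.93), Msi2 (1.42) and Gata2 (0.88) rose, and adjusted over the list alone 5 were higher and 1 lower (adjusted p = 0.49 with an estimated correlation, fry 0.048). Kit and Gata2 were also the 2 that rose among 12 basophil and mast cell genes, with 3 higher and 1 lower adjusted over the list alone. Under library totals alone 16 reticulocyte genes, 2 globins and 1 platelet gene were higher, 2 progenitor markers were higher and 1 lower, and 1 basophil and mast cell gene was higher and 2 lower.

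Of 18 genes of the integrated stress response at 6 h, Asns (2.67, SE 0.28), which makes asparagine, Atf5 (1.88), Shmt2 (1.62) and Mthfd2 (1.19) rose with Slc3a2 (0.97), 5 in all. Adjusted over the list alone 8 were higher and 1 lower, and the median was 0.11 (adjusted p = 0.49 with an estimated correlation, fry adjusted p = 0.013). Of 42 interferon-stimulated genes 8 rose, and 11 adjusted over the list alone. Oas3 (1.26), Isg15 (1.68), Usp18 (1.45) and Ifit1 (1.29) led a list whose median was 0.09 (adjusted p = 0.65 with an estimated correlation). With library totals alone 4 stress response genes were higher and 3 lower, and 6 interferon genes were higher and 4 lower. Isg15, a ubiquitin-like modifier, went from 72.1 ± 8.39 to 232 ± 28.5 CPM (SD, n = 3).

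The cell cycle, ribosomal, oxidative phosphorylation and mitochondrial mRNA lists were called toward higher as well, each with adjusted p = 0.65 with an estimated correlation. Of 50 cell cycle genes, Ube2c (2.03), Nusap1 (2.20) and E2f2 (1.62) rose, and 4 adjusted over the list alone. Of 77 ribosomal protein genes, 11 rose, and adjusted over the list alone 33 were higher and 1 lower, with Rpl7 (1.19) and Rpl27 (0.76) among them. Of 39 nuclear oxidative phosphorylation genes, Uqcrc2 (1.09), Cox7a2 (1.60) and Uqcrh (1.64) rose, and 6 adjusted over the list alone. Of 12 mitochondrial mRNAs 0 passed over all genes in edgeR, and 1 adjusted over the list alone. The ribosomal list had 2 genes higher and 1 lower with library totals alone (median 0.06 against 0.52), where 3 cell cycle genes were higher and 0 lower, and 3 oxidative phosphorylation genes were higher and 1 lower. The NK cell list (median 0.25) had 0 of 30 genes past either threshold, with adjusted p = 0.77 with an estimated correlation.

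Other genes and lists were lower at 6 h. Clec10a, a lectin of macrophages and dendritic cells and the only 1 of 16 dendritic cell genes to pass, over all genes or adjusted over the list alone, fell from 4.00 ± 2.04 to 0.350 ± 0.127 CPM (-3.44, SE 0.59, adjusted p = 0.0037). Il6st, the signal-transducing subunit of the interleukin-6 receptor, fell from 51.5 ± 8.95 to 14.9 ± 3.26 CPM (-1.79, SE 0.32, adjusted p = 0.0048). Of 20 classical monocyte genes, Ccr2 (-0.63) fell, and 1 adjusted over the list alone (list median -0.40, adjusted p = 0.49 with an estimated correlation). Of 23 immediate early genes, Atf3 (-1.34) fell, and 5 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Of 12 MHC class II genes 0 passed either way, with a median of -0.55 (adjusted p = 0.65 with an estimated correlation). Under library totals alone 9 classical monocyte, 9 immediate early, 2 MHC class II and 1 dendritic cell gene were lower.

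The largest rises at 6 h, beside Slc4a5 (6.50), Hsd3b6 (4.50), Mapre3 (4.08), Gpd1 (3.83), Ccdc92b (3.41) and Runx1t1 (3.52), were in Cystm1 (5.001), Col18a1 (4.95), Rhbdf1 (4.57), Epb41l5 (4.26), Abca5 (3.96) and Nos2 (3.52), which makes nitric oxide. Col18a1 had 3 counts over the vehicle libraries and 94 at 6 h, a ratio of 35.8 (95% exact binomial interval 11.9 to 177). Rhbdf1, Epb41l5 and Abca5 had 9, 7 and 6 vehicle counts, with ratios at 6 h of 24.8 (12.8 to 54.9), 20.2 (9.53 to 51.4) and 16.6 (7.31 to 46.4). Over the alternatives tried for named genes the log2 fold change of Nos2 ran from 2.90 to 6.78 and that of Abca5 from 2.62 to 4.78. That of Slc4a5 ran from 5.94 to 10.2. The other named falls were in the bitter taste receptor genes Tas2r143 (-2.77) and Tas2r135 (-1.95), which are neighbours on chromosome 6, and in Fanca (-2.37), Urb1 (-2.36), Usp50 (-2.30), Slc26a6 (-2.03), Sh3pxd2b (-1.92), Il1bos (-1.92), Eogt (-1.83) and Rusc2 (-1.79). With 1 of the 12 libraries left out in turn, Il1bos lost its call in 9 fits, Usp50 and Slc26a6 in 8, Rusc2 in 7, Tas2r135 in 6, Abca5 in 5, Tas2r143, Urb1 and Sh3pxd2b in 4, Col18a1, Epb41l5, Nos2 and Fanca in 3 and Eogt in 2. Il1bos also lost it with the replicate block.

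Other lists without a camera call at 6 h had single members past the threshold. These were Tal1 (0.72) and Gata2 among 11 tested PRC2-repressed developmental regulators (3 adjusted over the list alone, list median 0.30 and mean -0.14). They were also Cdkn2c (2.23) and Phlda3 (1.28) among 17 cell cycle inhibitors and p53 targets, and Nos2 and Saa3 (1.95) among 22 inflammatory genes. Adjusted over the list alone, 2 and 3 genes rose in these 2 lists. Mmp8 (1.38), Cd36 (1.93), Lat (1.25) and Hsp90ab1 (0.84) rose in the lists for neutrophils, nonclassical monocytes, T cells and heat shock, where 2, 1, 1 and 1 rose adjusted over the list alone. Camera adjusted p for these lists was 0.29 to 0.93. Of the developmental regulators 0 passed with library totals alone, with a median of -0.15, and 1 cell cycle inhibitor or p53 target was higher and 4 were lower, with a median of -0.40. In this scaling the inflammatory list had 1 higher and 1 lower, and those for neutrophils, T cells and heat shock, whose medians also turned negative, had 0, 1 and 0 higher and 3, 0 and 1 lower. The nonclassical monocyte list had 1 higher and 1 lower.

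Whether more of the called genes were higher or lower at 6 h depended on the scaling. With library totals alone, chosen after seeing the data, the median gene was at -0.50, a shift of -0.46, with 344 genes higher and 1488 lower. All 648 genes called with TMM kept their direction and 435 their call, the 24 named for the size of their change among them. The medians of the NK cell, interferon, cell cycle, mitochondrial mRNA, oxidative phosphorylation and stress response lists turned negative. The count was 250, 239 and 355 without vehicle replicate 1, 2 or 3, 299, 358 and 329 without 6 h replicate 1, 2 or 3, and 1205 and 1266 without 24 h replicate 1 or 3. With the reticulocyte covariate, also added later, it was 64. The covariate itself separated these groups (8.99 to 9.13 at 6 h and 7.58 to 7.88 in vehicle), so it overlaps with the group difference. The lower count therefore does not show that the changes follow reticulocytes.

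At 24 h, 14 genes were higher than in vehicle and 0 were lower in edgeR, where 444 were lower at an unadjusted p under 0.05, DESeq2 called 13 and limma-voom 0. They included the 7 genes called at all 3 times. Syt13, a synaptotagmin, rose from 5.24 ± 1.64 to 23.3 ± 2.97 CPM, and Rims3, a presynaptic protein, from 14.3 ± 2.30 to 62.4 ± 18.9 CPM (SD, n = 3). The 12 named rises were in Slc4a5 (4.35), Hsd3b6 (3.72), Car8 (3.25), Mapre3 (3.12), Runx1t1 (2.45), Cpne8 (2.26), Syt13 (2.15, SE 0.28, adjusted p = 0.0073), Rims3 (2.12, SE 0.32, adjusted p = 0.016), Ptprn (2.02), Rragd (1.75), Scd1 (1.66) and Nif3l1 (1.57). Leaving out 1 of the 12 libraries in turn, beside the losses given above, ended the call of Nif3l1 in 10 fits, of Cpne8, Rims3 and Ptprn in 4 and of Syt13 in 1. The 3 lower genes with the smallest p did not pass: Sart1 (-2.14, adjusted p = 0.12), Cnot2 (-0.78, adjusted p = 0.13) and Rell1 (-0.86, adjusted p = 0.16).

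Platelet genes were toward higher at 24 h, with 0 of 30 passing over all genes and 8 adjusted over the list alone, and Thbs1 at 0.97 (adjusted p = 0.12). The list had adjusted p = 0.98 with an estimated correlation, and 1 gene past the threshold with library totals alone. Stem and progenitor markers were also toward higher, with 0 of 15 and 3 adjusted over the list alone, and Adgrg1 at 0.95 (adjusted p = 0.052). The list had adjusted p = 0.71 with an estimated correlation. Mature neutrophil (median -0.35), secondary granule (-0.36) and immediate early genes (-0.20) were toward lower, with 0 members past either threshold in edgeR. These 3 lists had adjusted p = 0.98 with an estimated correlation. The neutrophil list lost its call and turned direction without vehicle replicate 3 (adjusted p = 0.95). The gene count was 7, 3 and 6 without vehicle replicate 1, 2 or 3, 39, 4 and 112 (36 higher and 76 lower) without 24 h replicate 1, 2 or 3, 83 in DESeq2, 7 in limma-voom, and 1 with only the 2 groups compared.

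The drug targets were measured at every time. Ezh2 stood at 280 ± 22.6 CPM in vehicle, 213 ± 16.8 at 1 h, 408 ± 33.4 at 6 h and 219 ± 156 at 24 h (SD, n = 3). Its log2 fold change was -0.40 (SE 0.36), 0.54 (SE 0.36) and -0.35 (SE 0.36). Ezh1 had -0.06 (SE 0.20), 0.21 (SE 0.20) and 0.16 (SE 0.20), Eed had 0.09 (SE 0.20), 0.10 (SE 0.20) and -0.18 (SE 0.20), and Suz12 had -0.33 (SE 0.25), 0.08 (SE 0.25) and -0.61 (SE 0.25). Of the 16 tests against vehicle, the mean of the times included, 0 passed in edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05. The lowest adjusted p in edgeR was 0.43. Of the 12 tests between times, 0 passed in edgeR, DESeq2 or limma-voom and 3 had an unadjusted p under 0.05. These were Ezh2 for 6 h against 1 h (0.94, adjusted p = 0.17) and 24 h against 6 h (-0.90, adjusted p = 0.16), and Suz12 for 24 h against 6 h (-0.69, adjusted p = 0.12). No transcript change of these genes passed the threshold at this depth and spread. The model shares its spread over the 4 groups. For Ezh2 the SD at 24 h was far above those of the other groups. Its SE at 1 and 6 h therefore carries the scatter at 24 h, and these results do not show that Ezh2 was unchanged.

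Any difference among 1, 6 and 24 h was found for 101 genes in the F test. This count was 64 and 22 without vehicle replicate 1 or 2, 13, 21 and 8 without 1 h replicate 1, 2 or 3, 8, 27 and 9 without 6 h replicate 1, 2 or 3, 343, 9 and 1972 without 24 h replicate 1, 2 or 3, and 17 with the reticulocyte covariate.

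From 1 to 6 h, 18 genes rose and 48 fell. Fkbp5 fell by 2.15 (SE 0.32, adjusted p = 0.021) and the clock gene Per1 fell by 2.57 (SE 0.52, adjusted p = 0.0498). Il6st (-2.17), Clec10a (-3.07), Tas2r143 (-3.53) and Tas2r135 (-2.30) also fell. Genes that rose included Ceacam10 (2.09), Mpst (1.70), Rph3al (1.59), Aff3 (1.47), Asns (1.43) and Isg15 (1.37). Of the 22 glucocorticoid-response genes 5 fell, Fkbp5, Klf9 (-1.02), Tsc22d3 (-0.98), Ddit4 (-1.25) and Per1, and adjusted over the list alone 8 were lower and 1 higher (adjusted p = 0.50 with an estimated correlation). Under library totals alone 9 were lower. When 1 of the 12 libraries was left out in turn, Tas2r135 and Aff3 lost their call in 10 fits, Rph3al and Isg15 in 9, Per1, Clec10a, Ceacam10 and Asns in 8, Tas2r143 in 6, Mpst in 5, Fkbp5 in 4 and Il6st in 3. Per1, Ceacam10 and Aff3 also lost it with DESeq2 size factors, and Clec10a and Tas2r135 with the replicate block.

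Camera called 16 lists between 6 and 1 h, of which 12 were toward higher and 4 toward lower, and 0 held with an estimated correlation, where the adjusted p was 0.50 to 0.64. Ribosomal protein genes had 0 of 77 past the threshold over all genes in edgeR and 51 adjusted over the list alone. Reticulocyte genes had 0 of 35 and 19 adjusted over the list alone. With library totals alone the median gene moved by -0.43, to 17 genes higher and 657 lower, with all 66 genes keeping their direction. The medians of 4 of the 16 lists, those for mature neutrophils, NK cells, interferon and oxidative phosphorylation, went from higher to lower. The count was 37 and 31 without vehicle replicate 1 or 2, 8, 11 and 4 without 1 h replicate 1, 2 or 3, 4, 19 and 10 without 6 h replicate 1, 2 or 3, 1006, 33 and 1285 without 24 h replicate 1, 2 or 3, and 1 with the reticulocyte covariate. More genes were higher than lower in several alternatives: 583 against 423 without 24 h replicate 1, 912 against 373 without 24 h replicate 3, 405 against 337 in DESeq2, 809 against 418 with no filter and 1088 against 632 with only the 2 groups compared. The balance of directions from 1 to 6 h is therefore not settled. The reticulocyte list means at 6 h lay wholly above those at 1 h. The lower count with that covariate therefore does not show that the changes follow reticulocytes.

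From 1 to 24 h, 3 genes fell and 0 rose in edgeR, where 459 were higher at an unadjusted p under 0.05, DESeq2 called 4 higher and limma-voom 0. Irf2bp2, a corepressor, fell by 1.21 (SE 0.18, adjusted p = 0.041), from 117 ± 16.4 to 50.6 ± 8.19 CPM. It lost its call in 8 of the 12 fits that left out 1 library and with the replicate block. The others were Gm49838 (-2.99) and Gm22146 (-3.15), both inside Fkbp5 and chosen for naming after their values were seen. The higher genes with the smallest p, Hrh2 (0.87, adjusted p = 0.18), Cad (1.78, adjusted p = 0.32) and Rnf40 (0.94, adjusted p = 0.39), did not pass. Of the 22 glucocorticoid-response genes 0 passed over all genes and 9 were lower adjusted over the list alone (camera adjusted p = 7.5e-11, with adjusted p = 0.30 with an estimated correlation). The count was 7 and 1 without vehicle replicate 1 or 2, 1 and 0 without 1 h replicate 1 or 3, 1 without 6 h replicate 2, 0 without 24 h replicate 1 or 2, and 205 without 24 h replicate 3, with 691 to 975 genes at an unadjusted p under 0.05 where it was 0. The other lists called were reticulocyte and clock genes toward lower (adjusted p = 0.95 and 0.30 with an estimated correlation), and platelet and histone genes toward higher (both 0.95). Adjusted over the list alone, 0 reticulocyte, 1 clock, 1 platelet and 0 histone genes passed.

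From 6 to 24 h, 68 genes rose and 167 fell. Of the 35 reticulocyte genes 8 fell, Car2 (-1.90, SE 0.41) among them, with 31 lower adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). Of the other lists toward lower, Hbb-bt (-1.47) and Hbb-bs (-1.47) fell among the globins, and Asns (-1.87) in the stress response. In the interferon list 5 genes fell, led by Isg15 (-1.54), and in the cell cycle list 3, led by E2f2 (-1.74). In the haem list 3 fell, Alad (-1.15) among them, and Rpl23 (-0.96) fell in the ribosomal list. Adjusted over each list alone, 2, 3, 11, 7, 7 and 30 genes were lower in these 6 lists, and their adjusted p with an estimated correlation was 0.54 to 0.78. Among MHC class II genes Ciita (1.95), their transactivator, rose, with 4 adjusted over the list alone (adjusted p = 0.67 with an estimated correlation). Under library totals alone 14 reticulocyte genes and 2 globins were lower, 1 haem gene was higher and 4 lower, 1 ribosomal gene was higher and 1 lower, and 6 MHC class II genes were higher.

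The 11 PRC2 subunits were toward lower from 6 to 24 h with 0 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.66 with an estimated correlation). Of the largest rises, Tdrd6 (5.15), Tas2r143 (3.08), Mettl17 (2.66), Disc1 (2.30) and Tas2r135 (2.07) stood beside Ciita, and Serpini1 (-3.19), Rph3al (-2.30), Slc4a5 (-2.15) and Atg4a (-1.91) beside Car2 among the falls. Of the 12 fits that left out 1 library, the call was lost in 11 for Tas2r135 and Serpini1, 10 for Ciita, Atg4a and Car2, 9 for Tdrd6, Tas2r143 and Mettl17, 8 for Slc4a5, 7 for Disc1 and 3 for Rph3al. In the ribosome biogenesis list, Fbl (1.15) and Cad (1.56) rose, and 6 genes were higher with library totals alone. With library totals alone the median gene shifted by 0.53, to 2692 genes higher and 259 lower, with all 235 genes keeping their direction. The medians of 6 of the 13 lists called turned from lower to higher: PRC2 subunits (-0.29 to 0.17), interferon (-0.11 to 0.43), cell cycle (-0.37 to 0.09), stress response (-0.35 to 0.18), NK cell and oxidative phosphorylation. In the interferon list 8 genes were then higher and 6 lower. The direction of fold changes in these lists from 6 to 24 h thus depends on the scaling and is not settled. Because the median gene shifted as well, the turns do not bear on a list's place relative to other genes, which camera compares. The count was 136, 54 and 100 without vehicle replicate 1, 2 or 3, 27, 63 and 26 without 1 h replicate 1, 2 or 3, and 2, 13 and 0 without 6 h replicate 1, 2 or 3. It was 0 without 24 h replicate 1 or 2, 2243 without 24 h replicate 3, and 0 with only the 2 groups compared, where 1963 genes had an unadjusted p under 0.05.

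Over all 7 contrasts, 10 of the 41 lists had no gene past the threshold and no camera call: B cell, plasma cell, eosinophil, innate lymphoid cell, azurophil granule, endothelial and stromal, urothelial and keratinocyte, cholesterol synthesis, MHC class I and PRC1 lists. In several of them few listed genes had enough counts to be tested. These were 8 of 30 B cell, 4 of 12 plasma cell, 4 of 21 endothelial and stromal and 4 of 23 urothelial and keratinocyte genes. A lack of calls there is weak evidence of no change. Camera with the preset correlation made 70 calls over lists and contrasts, and 0 were made with an estimated correlation, where the lowest adjusted p was 0.30. Of the 58 passing genes that the naming rule picked, 28 overlap another annotated gene of the count table, and the strand of the reads is not given in the sources used here.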

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

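Of the tests here, the reticulocyte covariate, the count of keratins, the comparison within the reticulocyte list and both glucocorticoid tests were chosen after the result was seen. Effects that differed between collection times, by a test of the difference itself, numbered 66 genes for 6 h against 1 h, 3 for 24 h against 1 h, 235 for 24 h against 6 h and 101 for any difference among the times. Of the genes named against vehicle, those that differed between 6 and 1 h were Clec10a (-3.07), Tas2r143 (-3.53), Tas2r135 (-2.30) and Il6st (-2.17). Between 24 and 6 h they were Slc4a5 (-2.15), Rragd (-1.56), Ccdc92b (-1.63), Pcx (-1.59), Runx1t1 (-1.07) and Scd1 (-1.12), lower at 24 h, and Tas2r143 (3.08), Tas2r135 (2.07) and Rims3 (1.29), higher. The count for 24 h against 6 h fell to 0 in edgeR without 6 h replicate 3, 24 h replicate 1 or 24 h replicate 2, with 1963 to 2514 genes at an unadjusted p under 0.05, and rose to 2243 without 24 h replicate 3.

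Other splits of the libraries were counted for each result. In 3 against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, had as many calls in each case. The real counts and highest others were 26 and 0 at 1 h, 648 and 0 at 6 h, 14 and 0 at 24 h, 66 and 1 for 6 h against 1 h, 3 and 0 for 24 h against 1 h, and 235 and 0 for 24 h against 6 h. For the mean of the times, 3 of 100 splits had as many as the real 125, and the highest other split had 761. These splits shuffled all 4 group labels, so the time groups were broken up along with the vehicle group. They do not isolate treatment from time, and chance is not excluded for this contrast. For any difference among times, 7 of 100 splits had as many as the real 101, the highest with 925, so chance is not excluded. The other splits with as many calls as the real one, in these 2 cases, kept the 6 h libraries together or joined 2 of them with 24 h replicate 3. These are the 4 libraries highest in reticulocyte genes, so a structure of the samples may lie behind these splits, which was not tested.

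The 14 genes higher at 24 h, with 7 of them called at all 3 times, were weighed first. With the reticulocyte covariate 14 were still called. The list means at 24 h (7.01, 7.56 and 8.66) lay on both sides of those in vehicle (7.58, 7.61 and 7.88). The covariate therefore had little group difference to remove, and this test does not decide on reticulocyte RNA. In the lowest of 3 other scalings 14 were still called. The median gene shifted by -0.001 with DESeq2 size factors, -0.00045 without haemoglobin genes and 0.063 with library totals alone. The named rises at 24 h were 1.57 to 4.35. The calls thus did not depend on the choice among these scalings. Scalings so alike could hardly have ended them, so the test does not decide on scaling in general. Keratin counts, abundant in epithelial tumour cells, summed to 0.232% of those of Runx1t1 in the 9 treated libraries (10 against 4314). This would argue against reads from the human xenograft as the source of the Runx1t1 counts only under an assumption. Human reads of keratins and of Runx1t1 would have to be counted on the mouse genes alike, which was not measured. The check therefore does not decide for Runx1t1. The other genes were not set against keratins, so it does not decide for them either. Direct action of CPI-0209 on blood cells or their precursors may explain these genes, as a hypothesis found on these data that was not itself tested, and a change in another cell type stays open.

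The rise of reticulocyte genes at 6 h was weighed next. Of its 17 called genes 16 were still called in the lowest of 3 other scalings, against scaling as the cause. Relative to the list mean, 23 of 35 members differed between 6 h and vehicle (limma adjusted p under 0.05), with Epb42 at 1.81 and Fech at -0.94. Equal rises would be forecast for a larger share of reticulocytes with unchanged content only if reticulocytes alone held these transcripts. Members also present in other blood cells would rise less, so this test cannot exclude a larger share as the whole cause. A younger or otherwise altered red cell population, with or without a larger share, may be a candidate explanation, and it was not tested. The highest 24 h library had a list mean of 8.66, below the 3 libraries at 6 h.

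The glucocorticoid-response genes at 1 h were weighed last. The list mean was 6.22 ± 0.11 at 1 h and 5.63 ± 0.08 at 24 h (SD, n = 3), a difference of -0.59 (SE 0.13). Collections 1 and 24 h after a dose fall near the same clock hour if all mice were dosed at the same hour. Clock time alone would then forecast similar list means at both times. The list was taken up because it was higher at 1 h than at the other times. The difference was thus part of the pattern and is no independent test, so clock time is not decided. Dosing or handling shortly before collection cannot be told apart from an action of the drug, because the rise over vehicle (0.56) would need vehicle mice collected 1 h after their last dose, and their time is not in the labels.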

How the results depend on the processing

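The reticulocyte covariate and library totals alone were chosen after seeing the data. Over the passing genes that the naming rule picked, direction was never reversed in the settings tried for them. Of 91 calls, 91 passed in DESeq2 and without haemoglobin genes, 87 with DESeq2 size factors, and 85 with the replicate block. With 1 library left out, 683 passed and 409 did not. Limma-voom and only the groups compared were not among these settings. With only the groups compared, 1 of the 14 genes called at 24 h, 5 of the 125 in the mean and 0 of the 235 for 24 h against 6 h kept their call. Replicate numbers did not pair the libraries: 2 of 18 same-number pairs correlated above 0.1. DESeq2 size factors and leaving out haemoglobin genes kept each gene count within 1.5 times. Where no value or construction below shows it, the cause was not tested.

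Counts are given in the order 1 h, 6 h, 24 h and mean against vehicle (26, 648, 14 and 125), 6 h against 1 h (66), 24 h against 1 h (3), 24 h against 6 h (235) and any difference (101). No filter gave 288, 1265, 237, 499, 1227, 107, 1477 and 1788. DESeq2 gave 152, 1160, 83, 367, 742, 27, 1125 and 1250. Limma-voom gave 17 at 1 h, 7 at 24 h, 5 for 24 h against 1 h, 729 for 24 h against 6 h and 365 for any difference. Only the groups compared gave 204, 1382, 1 and 5 (the last with all 12 libraries, the 9 treated ones as 1 group), then 1720 for 6 h against 1 h, 0 for 24 h against 6 h (edgeR, 1963 at an unadjusted p under 0.05) and 17 for any difference. The replicate block gave 1 for 24 h against 1 h, 418 for 24 h against 6 h and 226 for any difference. The stricter filter gave 445 for 24 h against 6 h. The reticulocyte list mean itself separated the 6 h libraries from those of vehicle and 1 h. Lower counts with it as a covariate in these comparisons therefore do not decide on reticulocyte RNA. The reticulocyte covariate gave 305, 64, 166 and 316, of which 26, 36, 14 and 96 were genes called without it (138 higher and 167 lower at 1 h, 42 and 22 at 6 h, 80 and 86 at 24 h and 157 and 159 in the mean, where the main fit had 24 and 2, 543 and 105, 14 and 0, and 118 and 7), and 1, 1 and 17 for 6 h against 1 h, 24 h against 6 h and any difference.

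Library totals alone gave 65, 1832 and 26 at 1, 6 and 24 h, and 674, 2951 and 1319 for 6 h against 1 h, 24 h against 6 h and any difference. The share of calls that were higher went from 83.8% to 18.8% at 6 h, from 27.3% to 2.52% for 6 h against 1 h and from 28.9% to 91.2% for 24 h against 6 h. The median of all genes shifted by -0.46, -0.43 and 0.53 in these, and by -0.14 in the mean. Every called gene kept its direction, and 22, 435, 14, 100, 59, 2 and 195 kept their call in the 7 contrasts.

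Leaving out 1 library gave 7 (without vehicle replicate 2) to 165 (24 h replicate 3) genes at 1 h, 239 (vehicle replicate 2) to 1266 (24 h replicate 3) at 6 h, 3 (vehicle replicate 2) to 112 (24 h replicate 3) at 24 h, and 14 (vehicle replicate 2) to 357 (24 h replicate 1) in the mean. It gave 4 (1 h replicate 3 or 6 h replicate 1) to 1285 for 6 h against 1 h, 0 (1 h replicate 3, or 24 h replicate 1 or 2) to 205 for 24 h against 1 h, 0 (6 h replicate 3, or 24 h replicate 1 or 2) to 2243 for 24 h against 6 h, and 8 (1 h replicate 3 or 6 h replicate 1) to 1972 for any difference, the highest each time without 24 h replicate 3. In edgeR, 691 to 2514 genes had an unadjusted p under 0.05 where the count was 0.

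With an estimated correlation, 0 lists were called in each of the 7 contrasts by camera, where the preset gave 7, 15, 5, 9, 16, 5 and 13. No filter called 8 lists for 24 h against 1 h. Leaving out 1 library gave 6 to 12 lists at 1 h, 3 to 6 at 24 h and 4 to 8 for 24 h against 1 h. The mature neutrophil list ran from adjusted p = 1.1e-09 to 0.60 at 1 h and 1.7e-10 to 0.95 at 24 h, turning direction without vehicle replicate 3. Targets that did not pass changed sign: Ezh1 at 1 h (-0.25 to 0.10), Suz12 at 6 h (-0.13 to 0.19), Ezh2 at 24 h (-1.07 to 0.027) and in the mean (-0.31 to 0.057), Eed at 24 h (-0.39 to 0.017) and in the mean (-0.067 to 0.067, and -0.0012 with the replicate block). Over genes with a mean log2 CPM of at least 1, correlations were 0.484 for 1 and 6 h, 0.579 for 1 and 24 h and 0.452 for 6 and 24 h. Counts of a few reads in vehicle limit the folds of Slc4a5, Col18a1, Abca5, Epb41l5 and Rhbdf1.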

Other observations

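The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x had 0 counts in all 12 libraries, which allows up to 0.462 CPM in the library with the lowest total and 0.301 CPM in that with the highest. Hbb-bh2 had counts of 1, 3 and 0 at 1 h and 0, 1 and 6 at 6 h, and 0 in each vehicle and 24 h library. Of the 39 Hox cluster genes 1 was expressed enough to be tested. Neither list was tested as a set.

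A hypothesis chosen after the values were seen was that the Ezh2 level may follow the reticulocyte share of a library. Within groups, Ezh2 correlated with the reticulocyte list mean at r = 0.95 (permutation p = 0.069) and rho = 0.54 (permutation p = 0.19) over 12 libraries, 1 relation tested. Without 24 h replicates 1 and 3, r was 0.26, so the relation rests on those 2 libraries and stays undecided.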
